A study of Mus musculus with 9 samples.

How the data were processed

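Poly(A) RNA was extracted with a QIAGEN RNeasy kit and made into libraries with an NEBNext Ultra II kit, per the labels' protocols. The samples were 9 libraries of cells, neural by label, differentiated from mouse embryonic stem cells, 3 each from cells expressing HA-tagged H4WT, H4K91R or H4K91Q. The deposited values are expected counts per gene, whole numbers that Salmon 0.8.2 and the genome build mm10 are named for, per the submitters' processing notes. Those notes also name DESeq2, without a version or a role. Salmon estimates counts that need not be whole, and whether the authors rounded them before they deposited the table is not recorded. The annotation behind the counts, read trimming, read length and strand setting are not given in the sources used here. Salmon divides reads that match several genes among them, so genes with near-identical copies carry uncertain values.

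The table held 24100 Entrez gene IDs, none duplicated, and all values were whole. A RefSeq gene table for GRCm38.p6, the patch release of mm10, matched 24045 IDs to a symbol, and its coordinates are used throughout. The other 55 IDs held 0.0370% to 0.0584% of the counts of a library and stayed in the tests by ID. Mitochondrially encoded genes were not analysed here. Total counts per library ran from 8970553 to 28887501, with a median of 16364686. A count of 0, which allows up to 3 counts, corresponds to at most 0.111 to 0.367 CPM on the TMM scale, depending on the library, and such limits cover counting error only.

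Genes were filtered with filterByExpr by group in edgeR 4.0.16 (R 4.3.3, minimum count 10), which kept 14761. Libraries were scaled by TMM, with factors from 0.911 to 1.06. A quasi-likelihood model with 1 mean per group was fitted to all 9 libraries, so that the groups shared 1 estimate of the spread, a biological coefficient of variation of 8.82%. Tests were two-sided, and a gene counted as changed at a Benjamini-Hochberg adjusted p below 0.05 over the 14761 genes. The contrasts were H4K91R against H4WT, H4K91Q against H4WT, H4K91Q against H4K91R and a joint test over the 3 groups. The contrast between the mutants is also the test of whether their effects against H4WT differ. Calls shared by the mutants were set beside the overlap of independent lists and beside 20 simulated pairs of unchanged groups with the same controls.

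The test was tried on simulated counts for real genes with the means and library sizes of these samples, 50 genes at each fold. For H4K91R against H4WT (14646 genes) it recovered 4% of genes changed 1.2-fold, 62% at 1.5-fold, 84% at 2-fold and 94% at 4-fold, and it called 2 unchanged genes. For H4K91Q against H4WT (14656 genes) it recovered 4%, 64%, 84% and 96%, and it called 4 unchanged genes. Far fewer genes were changed in the simulation than were called in the data, which makes the adjusted threshold stricter in the simulation. The shares recovered are thus not those of the real comparisons. In a simulated set of the 27 lists with 1 list raised 1.5-fold, the raised list was called and 0 others were. Genes were simulated independently of each other, so this does not show how the list test behaves where members move together.

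The tests, the alternatives, 27 gene lists and the rule for naming genes were fixed before the data were examined. The lists are pluripotency, primed epiblast, neural progenitor, proneural, neuronal, forebrain, midbrain and anterior hindbrain, Hox, glia, mesoderm, endoderm, surface ectoderm and epithelium, neural crest and mesenchyme, 2-cell-like, germline, imprinted, histone H4, H3.3 and heterochromatin machinery, p53 targets, cell cycle, interferon response, integrated stress and unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, retinoic acid targets, Wnt, BMP and Hedgehog targets, and RNA quality and stress. Of 741 listed names, 706 matched a symbol, 16 matched a synonym and 19 matched nothing. Lists were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a contrast. Each list was also tested with an estimated correlation and with fry, which asks whether its genes move one way and compares it with no other genes. Members were counted with p-values adjusted over all tested genes, and again adjusted over the list alone.

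The genes named were drawn from, for each mutant against H4WT, the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 2 CPM, a symbol that is no clone or model name, and no overlap of the groups' libraries. With 3 libraries against 3, chance parts 10% of genes so. Between the mutants the 5 largest each way were taken. From each list up to 3 called members per contrast with the smallest adjusted p and at least 1 CPM were added, and every histone H4 gene of at least 1 CPM. Where a list has no called member, up to 2 members were added with their values. Some genes that this rule takes are not reported here. Log2 changes carry the SE of the fit, and CPM carry the SD.

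The alternatives were RLE size factors, library size only, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, an absolute log2 change of at least 1, a fit of only the compared groups, and leaving out each library in turn. How far genes share sequence was measured as the share of a gene's 31-base words that occur in no other gene's transcripts, from the transcripts of GENCODE vM21. The test of a lower share of mesenchymal cells took 4 forms in turn, each set after the values were seen. The first compared the medians of contractile and of collagen and fibroblast genes by permutation, the second counted members of the neural crest and mesenchyme list without its contractile members, and the third counted the whole list. The first 2 argued against that explanation and the third left it open. The form reported asks that the counts with and without the contractile members both pass the bound. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).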

Results

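Poly(A) RNA was sequenced from cells, neural by label, that had been differentiated from mouse embryonic stem cells. The stem cells carried a stable PiggyBac transgene, delivered by a DNA transposon, for histone H4 with an HA tag, a short peptide recognised by an antibody. The tagged histone was wild type in the H4WT group. In the H4K91R and H4K91Q groups 1 lysine of the histone was replaced, by arginine and by glutamine. Arginine keeps the positive charge of lysine, and glutamine is often used as a stand-in for acetylated lysine. Each group had 3 libraries. The labels do not say whether the 3 replicates of a group are separate differentiations or separate lines. The p-value of a gene thus measures only the spread between these libraries. A list p-value with the preset correlation also takes the genes of a list as almost independent of each other. Total counts were 9081484, 28887501 and 8970553 for H4WT replicates 1, 2 and 3. They were 16704020, 12013052 and 9743050 for H4K91R, and 22661768, 19365792 and 16364686 for H4K91Q. Of the 24100 genes in the table, 14761 had enough counts to be tested.

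The libraries separated by group. H4WT lay apart from both mutants on the first principal component, which held 65.8% of the variance. The mutants separated from each other on the next component, with 12.1%. Across genes, which are not independent replicates, the correlation of log2 CPM (counts scaled to the TMM-adjusted library total) between libraries was 0.987 to 0.993 within groups. It was 0.978 to 0.986 between the mutants and 0.942 to 0.968 between H4WT and a mutant. In the test over all 3 groups, 7470 of 14761 genes differed (edgeR, Benjamini-Hochberg adjusted p below 0.05).

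**Figure D1:**
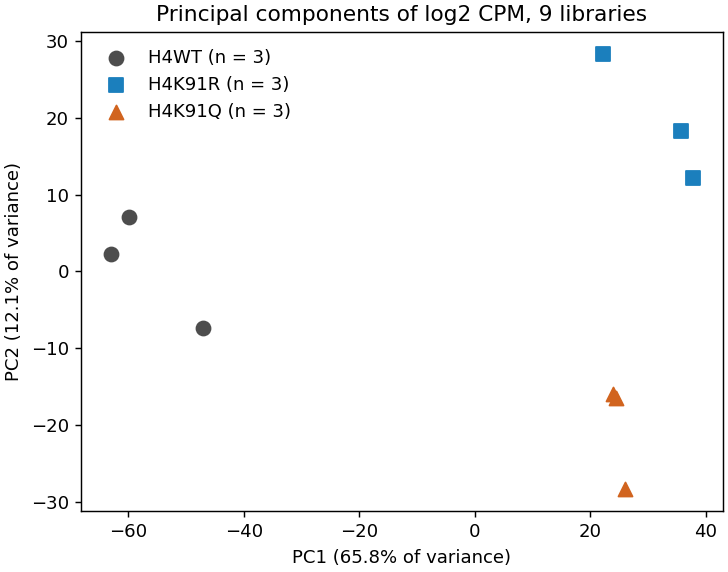
Principal components of log2 CPM over the 14761 tested genes, with 1 point per library and colour and shape for the group (n = 3 each). The first component (65.8% of the variance) parts the 3 H4WT libraries from the 6 mutant libraries, and the next (12.1%) parts H4K91R from H4K91Q.

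The comparison of H4K91R with H4WT asked which genes change with the arginine mutant in the bulk RNA of these cultures. They are neural by label but may hold other cell types. Col3a1, a collagen gene, stood at 2846, 3734 and 3373 CPM in H4WT, H4K91R and H4K91Q, and Tagln at 1547 CPM in H4WT. A changed mix of cells cannot be told apart from changes within cells here. Myh11, Acta2 and Actg2 were much lower in H4K91R, and most genes of the neuronal, proneural and neural progenitor lists were higher. Myh11, the smooth muscle myosin heavy chain (Entrez 17880, chromosome 16, 14194527 to 14292188), fell by 5.08 ± 0.27 on the log2 scale (SE, n = 3 libraries per group), from 77.1 ± 16.6 to 2.05 ± 1.41 CPM (mean ± SD). Acta2, smooth muscle actin (Entrez 11475, chromosome 19, 34240336 to 34255585), fell by 2.98 ± 0.14 on the log2 scale, from 2479 ± 218 to 315 ± 68.7 CPM. Fabp7, a fatty acid binding protein of radial glia (Entrez 12140, chromosome 10, 57784923 to 57788450), rose by 2.88 ± 0.13, from 44.7 ± 8.53 to 333 ± 42.9 CPM. The adjusted p of these genes was 4.73e-08, 3.51e-08 and 3.51e-08 (edgeR quasi-likelihood test, Benjamini-Hochberg). In all, 3092 genes rose and 3705 fell, and 1355 of the risen and 677 of the fallen genes changed at least 2-fold.

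Among the genes with the largest increases in H4K91R was Gpr83, a G protein-coupled receptor (Entrez 14608, chromosome 9, 14859880 to 14870789), at 4.98 ± 0.34 on the log2 scale. Its H4WT level was 0.416 ± 0.421 CPM, with no count in 1 H4WT library. Kera, the matrix proteoglycan keratocan (Entrez 16545, chromosome 10, 97606962 to 97613688), rose by 3.61 ± 0.43 and Ngfr, a neurotrophin receptor (Entrez 18053, chromosome 11, 95568818 to 95587698), by 3.40 ± 0.18. Abca9, Itih5, Grip2, Nhlh1 and Cd36 rose by 3.06 to 3.37. Among the largest decreases, Actg2, the smooth muscle gamma actin (Entrez 11468, chromosome 6, 83512909 to 83536251), fell by 4.35 ± 0.31 on the log2 scale. Lox, the lysyl oxidase that cross-links collagen and elastin (Entrez 16948, chromosome 18, 52516060 to 52529867), fell by 3.78 ± 0.19 on the log2 scale. Ltbp2, an extracellular matrix protein (Entrez 16997, chromosome 12, 84783212 to 84876558), fell by 4.01 ± 0.29 on the log2 scale. Siglecg, Map3k7cl, Jph2 and Cbr2 had log2 changes of -4.61, -4.45, -3.92 and -3.73.

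Lists of neural development rose in H4K91R, except the forebrain list. Of the neuronal list, 36 of 45 tested members rose and 1 fell (36 and 1 adjusted over the list alone), with a median log2 change of 1.90 (camera, adjusted p = 7.30e-15, and adjusted p = 0.204 with an estimated correlation). Dcx, a microtubule protein of migrating neurons (Entrez 13193, chromosome X, 143855842 to 143933396), rose by 2.36 ± 0.11, and Elavl3, a neuronal RNA-binding protein (Entrez 15571, chromosome 9, 22015005 to 22052146), by 2.66 ± 0.14. Of the proneural list, 20 of 25 tested members rose and 3 fell (20 and 3 adjusted over the list alone, camera adjusted p = 1.35e-07, and adjusted p = 0.112 with an estimated correlation). Its members include Myt1 at 2.93 ± 0.17. Of the neural progenitor list, 23 of 30 tested members rose and 2 fell (26 and 2 adjusted over the list alone, camera adjusted p = 9.52e-09, and adjusted p = 0.112 with an estimated correlation), among them Ncan at 2.72 ± 0.13 and Pou3f2 at 2.77 ± 0.16. Of the Hox genes, which pattern the hindbrain and trunk, 17 of 33 rose and 5 fell (17 and 5 adjusted over the list alone, camera adjusted p = 0.00240, and adjusted p = 0.204 with an estimated correlation), with Hoxb8 at 1.52 ± 0.094 and Hoxa5 at 2.03 ± 0.17. In the midbrain and anterior hindbrain list 9 of 13 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 7.11e-05, and adjusted p = 0.112 with an estimated correlation), with Pax2 at 2.34 ± 0.20 and En2 at 2.08 ± 0.22. In the glia list 8 of 12 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00297, and adjusted p = 0.204 with an estimated correlation), with S100b at 2.27 ± 0.34. The forebrain list did not pass. There 7 of 11 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0667), with Dlx1 at 2.52 ± 0.31.

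Of the retinoic acid targets 13 of 20 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.00297, and adjusted p = 0.112 with an estimated correlation). Aldh1a2, which makes retinoic acid, rose by 1.38 ± 0.16, and Cyp26a1, which breaks it down, fell by 0.96 ± 0.097 on the log2 scale. Of the Wnt, BMP and Hedgehog targets, a list that did not pass, 9 of 20 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0641), and Gli1, a Hedgehog target, rose by 2.14 ± 0.15. Of the imprinted genes 19 of 38 rose and 6 fell (20 and 7 adjusted over the list alone, camera adjusted p = 0.0199, and adjusted p = 0.207 with an estimated correlation), with Nnat at 1.79 ± 0.11, Dlk1 at 1.29 ± 0.094 and Slc38a4 at -1.35 ± 0.086. Of the primed epiblast genes 9 of 16 rose and 4 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.0363, and adjusted p = 0.309 with an estimated correlation), with Sall2 at 0.76 ± 0.091. The call of the imprinted list ended with library size scaling (adjusted p = 0.0857) and without H4WT replicate 2 (0.0508). That of the primed epiblast list ended with library size scaling (0.186), with thinning to equal totals, chosen after seeing the data (0.0636), and without H4WT replicate 3 (0.0551) or H4K91R replicate 2 (0.0529).

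The pluripotency, surface ectoderm and epithelium, endoderm and germline lists fell in H4K91R. Of the pluripotency list 1 of 28 tested members rose and 19 fell (1 and 19 adjusted over the list alone, camera adjusted p = 5.82e-04, and adjusted p = 0.323 with an estimated correlation), with Dppa2 at -1.75 ± 0.25 and Tfcp2l1 at -1.35 ± 0.17. Of the surface ectoderm and epithelium list 0 of 20 rose and 15 fell (0 and 17 adjusted over the list alone, camera adjusted p = 2.43e-05, and adjusted p = 0.204 with an estimated correlation), with Perp at -2.27 ± 0.12 and Dsp, a desmosome protein, at -1.49 ± 0.12. Of the endoderm list 3 of 24 rose and 14 fell (3 and 15 adjusted over the list alone, camera adjusted p = 0.00591, and adjusted p = 0.240 with an estimated correlation), with the basement membrane genes Lamb1 at -0.68 ± 0.074 and Sparc at -0.78 ± 0.067. Of the germline list 2 of 26 rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.0457, and adjusted p = 0.240 with an estimated correlation), with Ddx4 at -0.98 ± 0.12. The germline call ended without H4WT replicate 2 (adjusted p = 0.06) or 3 (0.0551) and without H4K91R replicate 1 (0.0644) or 3 (0.0587), and with libraries thinned to equal totals (0.0636). The mesoderm list did not pass. There 5 of 18 rose and 7 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.478), among them Meox2 at 1.67 ± 0.17 and Actc1, cardiac actin, at -2.56 ± 0.27. In the neural crest and mesenchyme list, which did not pass either, 8 of 23 rose and 6 fell (8 and 6 adjusted over the list alone, camera adjusted p = 0.733). Its members moved apart, with Ednrb at 2.30 ± 0.13 and Tagln, a smooth muscle actin-binding protein, at -3.14 ± 0.21. Its median was -0.056 and its mean -0.18, while the direction of the test was up, and the median turned to 0.13 with library size scaling. Of the 2-cell-like genes, which mark a rare state of stem cells, 1 of 4 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.687). Their median was 0.16 and their mean -0.45, with the test pointing up. The fall of Sp110 (-0.75 ± 0.28, edgeR, adjusted p = 0.0438) lay near the threshold, and its call was kept in 1 of the 9 fits without 1 library, the one without H4WT replicate 2. Without H4WT replicate 1 or 3 its adjusted p was 0.144 and 0.0633, without H4K91R replicate 1, 2 or 3 it was 0.106, 0.118 and 0.0613, and without H4K91Q replicate 1, 2 or 3 it was 0.0537, 0.0564 and 0.0538. The call also ended with RLE scaling (0.053), library size scaling (0.114), DESeq2 (0.130), limma-voom (0.0612), no filter on low counts (0.0650), the replicate block (0.0583), the compared groups only (0.0696) and thinning (0.0609).

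Stress and metabolic genes fell in H4K91R. Of the p53 targets 1 of 27 tested members rose and 21 fell (1 and 23 adjusted over the list alone, camera adjusted p = 5.02e-07, and adjusted p = 0.204 with an estimated correlation). Pmaip1, which promotes apoptosis (Entrez 58801, chromosome 18, 66458604 to 66465558), fell by 1.70 ± 0.081 on the log2 scale, and Mdm2, which degrades p53 (Entrez 17246, chromosome 10, 117688875 to 117710758), by 1.32 ± 0.090. Of the cholesterol synthesis genes 0 of 24 rose and 18 fell (0 and 18 adjusted over the list alone, camera adjusted p = 9.39e-05, and adjusted p = 0.204 with an estimated correlation). Of the hypoxia and glycolysis genes 4 of 23 rose and 14 fell (4 and 14 adjusted over the list alone, camera adjusted p = 0.00450, and adjusted p = 0.204 with an estimated correlation), with the glucose transporter Slc2a3 at -1.15 ± 0.083. Of the integrated stress and unfolded protein response genes 2 of 26 rose and 17 fell (2 and 17 adjusted over the list alone, camera adjusted p = 0.00120, and adjusted p = 0.204 with an estimated correlation), with Atf3 at -1.76 ± 0.11. Of the interferon response genes 1 of 32 rose and 13 fell (1 and 13 adjusted over the list alone, camera adjusted p = 0.0206, and adjusted p = 0.240 with an estimated correlation), with Tap1 at -0.91 ± 0.10. Of the RNA quality and stress genes, mostly immediate-early genes that answer handling, 1 of 12 rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.00450, and adjusted p = 0.291 with an estimated correlation), with Fosb at -2.17 ± 0.18. These handling genes moved together with the p53 and stress groups above. In the cell cycle list, which did not pass, 3 of 38 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.599). In the list of H3.3 and heterochromatin machinery, which did not pass either, 6 of 35 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.478).

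In the preset-correlation test 19 of the 27 lists passed for H4K91R, 9 upward and 10 downward, and none passed with an estimated correlation. TMM scaling set the balance of risen and fallen genes: with library size only, 5031 genes rose and 2013 fell, and the median over genes shifted by 0.18 on the log2 scale.

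The comparison of H4K91Q with H4WT asked the same question of the glutamine mutant. Myh11, Actg2 and Acta2 were again much lower, and most genes of the neuronal, proneural, neural progenitor and pluripotency lists were higher than in H4WT. Myh11 fell by 5.17 ± 0.26 on the log2 scale (SE, n = 3 libraries per group), to 2.14 ± 0.184 CPM (mean ± SD). Actg2 and Acta2 fell by 4.78 ± 0.31 and 3.34 ± 0.14 on the log2 scale. Elavl3 rose by 2.04 ± 0.13, from 13.1 ± 2.81 to 54.1 ± 1.07 CPM. Nanog, a core transcription factor of pluripotent cells (Entrez 71950, chromosome 6, 122707489 to 122714633), rose by 2.11 ± 0.24, from 3.80 ± 0.811 to 17.4 ± 4.28 CPM. The adjusted p was 7.61e-08 for Myh11, 3.42e-07 for Elavl3 and 1.47e-05 for Nanog (edgeR, Benjamini-Hochberg). In all, 3314 genes rose and 3516 fell, and 1237 of the risen and 616 of the fallen genes changed at least 2-fold.

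The genes with the largest increases in H4K91Q included Gpr83 at 5.01 ± 0.34, Scara5, a ferritin receptor (Entrez 71145, chromosome 14, 65666403 to 65764826), at 4.49 ± 0.54 and Hpgd, which inactivates prostaglandins (Entrez 15446, chromosome 8, 56294552 to 56321046), at 3.67 ± 0.29. Scara5 had no count in 1 H4WT library. Agtr2, an angiotensin receptor (Entrez 11609, chromosome X, 21484624 to 21488833), rose by 3.50 ± 0.22. Rtl3, Kera, S100b and Clec3b rose by 3.24 to 3.80. Among the largest decreases, Gpr149 and Gpr176, orphan receptors, changed by -4.55 and -4.02. Slc1a6, a glutamate transporter, changed by -3.78, and Siglecg, Map3k7cl and Ltbp2 by -4.79, -4.50 and -3.85.

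Lists of neural development rose in H4K91Q, except the forebrain list. Of the neuronal list 35 of 45 tested members rose and 2 fell (35 and 2 adjusted over the list alone, camera adjusted p = 5.86e-11, and adjusted p = 0.161 with an estimated correlation), with Dcx at 1.88 ± 0.11 and Crmp1, a protein of growing axons, at 1.54 ± 0.10. Dpysl3, a relative of Crmp1, fell by 1.29 ± 0.082 on the log2 scale. Of the proneural list 18 of 25 tested members rose and 3 fell (18 and 3 adjusted over the list alone, camera adjusted p = 2.06e-05, and adjusted p = 0.156 with an estimated correlation), with Myt1 at 2.52 ± 0.17. Of the neural progenitor list 22 of 30 tested members rose and 3 fell (23 and 3 adjusted over the list alone, camera adjusted p = 6.00e-07, and adjusted p = 0.156 with an estimated correlation). There Fabp7 rose by 2.36 ± 0.13, and Hes1, a Notch target, fell by 1.34 ± 0.082 on the log2 scale. Of the Hox genes 18 of 33 rose and 5 fell (18 and 5 adjusted over the list alone, camera adjusted p = 0.00666, and adjusted p = 0.172 with an estimated correlation), with Hoxb8 at 1.07 ± 0.093. Its call ended with library size scaling (adjusted p = 0.071). In the midbrain and anterior hindbrain list 9 of 13 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00112, and adjusted p = 0.156 with an estimated correlation), with Hoxa2 at 1.62 ± 0.18. In the glia list 8 of 12 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00163, and adjusted p = 0.165 with an estimated correlation), with S100b at 3.42 ± 0.30 and Nfia at 0.95 ± 0.10. In the forebrain list, which did not pass, 4 of 11 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.281). Dlx1 rose by 1.95 ± 0.32, and Dlx5 fell by 1.66 ± 0.17 on the log2 scale.

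Genes of pluripotency and of the primed epiblast rose in H4K91Q. Of the pluripotency list 17 of 28 tested members rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 0.00781, and adjusted p = 0.452 with an estimated correlation), with Esrrb at 1.77 ± 0.21 and Klf2 at 0.61 ± 0.081. The call of this list ended with library size scaling (adjusted p = 0.0563). Of the primed epiblast list 14 of 16 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 3.88e-05, and adjusted p = 0.156 with an estimated correlation), with Lef1 at 2.07 ± 0.22 and Zic2 at 1.34 ± 0.17. Of the retinoic acid targets 14 of 20 rose and 2 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.00367, and adjusted p = 0.156 with an estimated correlation), and Cyp26a1 fell by 1.03 ± 0.096 on the log2 scale. Of the Wnt, BMP and Hedgehog targets 13 of 20 rose and 4 fell (13 and 4 adjusted over the list alone, camera adjusted p = 0.0276, and adjusted p = 0.452 with an estimated correlation), with Gli1 at 1.96 ± 0.15. That call ended with library size scaling (adjusted p = 0.0879) and without H4WT replicate 1 (0.0585) or H4K91Q replicate 3 (0.0553). Of the imprinted genes 20 of 38 rose and 8 fell (21 and 8 adjusted over the list alone, camera adjusted p = 0.00666, and adjusted p = 0.161 with an estimated correlation), with Plagl1, a zinc finger transcription factor (Entrez 22634, chromosome 10, 13090832 to 13131694), at 2.20 ± 0.17 and the noncoding RNA H19 at 0.85 ± 0.067.

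Other lists fell in H4K91Q. Of the p53 targets 1 of 27 tested members rose and 24 fell (2 and 24 adjusted over the list alone, camera adjusted p = 2.86e-09, and adjusted p = 0.161 with an estimated correlation), with Pmaip1 at -1.48 ± 0.079 and Cdkn1a, an inhibitor of cell division, at -1.30 ± 0.10. Of the cholesterol synthesis genes 0 of 24 rose and 20 fell (0 and 21 adjusted over the list alone, camera adjusted p = 1.40e-06, and adjusted p = 0.156 with an estimated correlation). Of the integrated stress and unfolded protein response genes 2 of 26 rose and 18 fell (2 and 18 adjusted over the list alone, camera adjusted p = 3.61e-04, and adjusted p = 0.161 with an estimated correlation), with Sesn2 at -0.75 ± 0.088. Of the hypoxia and glycolysis genes 4 of 23 rose and 14 fell (5 and 15 adjusted over the list alone, camera adjusted p = 0.00352, and adjusted p = 0.161 with an estimated correlation), with P4ha1 at -0.76 ± 0.080. Of the RNA quality and stress genes 2 of 12 rose and 8 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.00353, and adjusted p = 0.269 with an estimated correlation), with Fosb at -2.68 ± 0.17 and Dusp1 at -1.04 ± 0.095, so that handling genes moved with the stress groups here too. Of the endoderm list 3 of 24 rose and 15 fell (3 and 16 adjusted over the list alone, camera adjusted p = 0.00112, and adjusted p = 0.167 with an estimated correlation), with Col4a1 at -1.03 ± 0.083. Of the surface ectoderm and epithelium list 2 of 20 rose and 10 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.0365, and adjusted p = 0.452 with an estimated correlation), with Perp at -1.96 ± 0.12. That call ended without H4WT replicate 2 (adjusted p = 0.0739) or H4K91Q replicate 1 (0.0713).

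Several lists did not pass in H4K91Q. In the neural crest and mesenchyme list 8 of 23 rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.355). Its median was 0.24 and its mean -0.039, with the test pointing up, and Tagln fell by 3.29 ± 0.21 on the log2 scale. In the mesoderm list 7 of 18 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.787). In the germline list 4 of 26 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.523), and in the 2-cell-like list 2 of 4 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.158). The call of Arg2, a member of the latter at 1.39 ± 0.32, ended without H4WT replicate 2 (adjusted p = 0.0565). Of the interferon response genes 7 of 32 rose and 7 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.787). Of the cell cycle genes 8 of 38 rose and 3 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.242). Of the H3.3 and heterochromatin machinery 12 of 35 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.0536). H3f3a, which encodes the histone variant H3.3, rose by 0.58 ± 0.088 in H4K91Q and by 0.47 ± 0.088 in H4K91R. In the preset-correlation test 18 of the 27 lists passed for H4K91Q, 11 upward and 7 downward, and none passed with an estimated correlation. With library size only, 5557 genes rose and 2069 fell, and the median over genes shifted by 0.17 on the log2 scale.

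**Figure D2:**
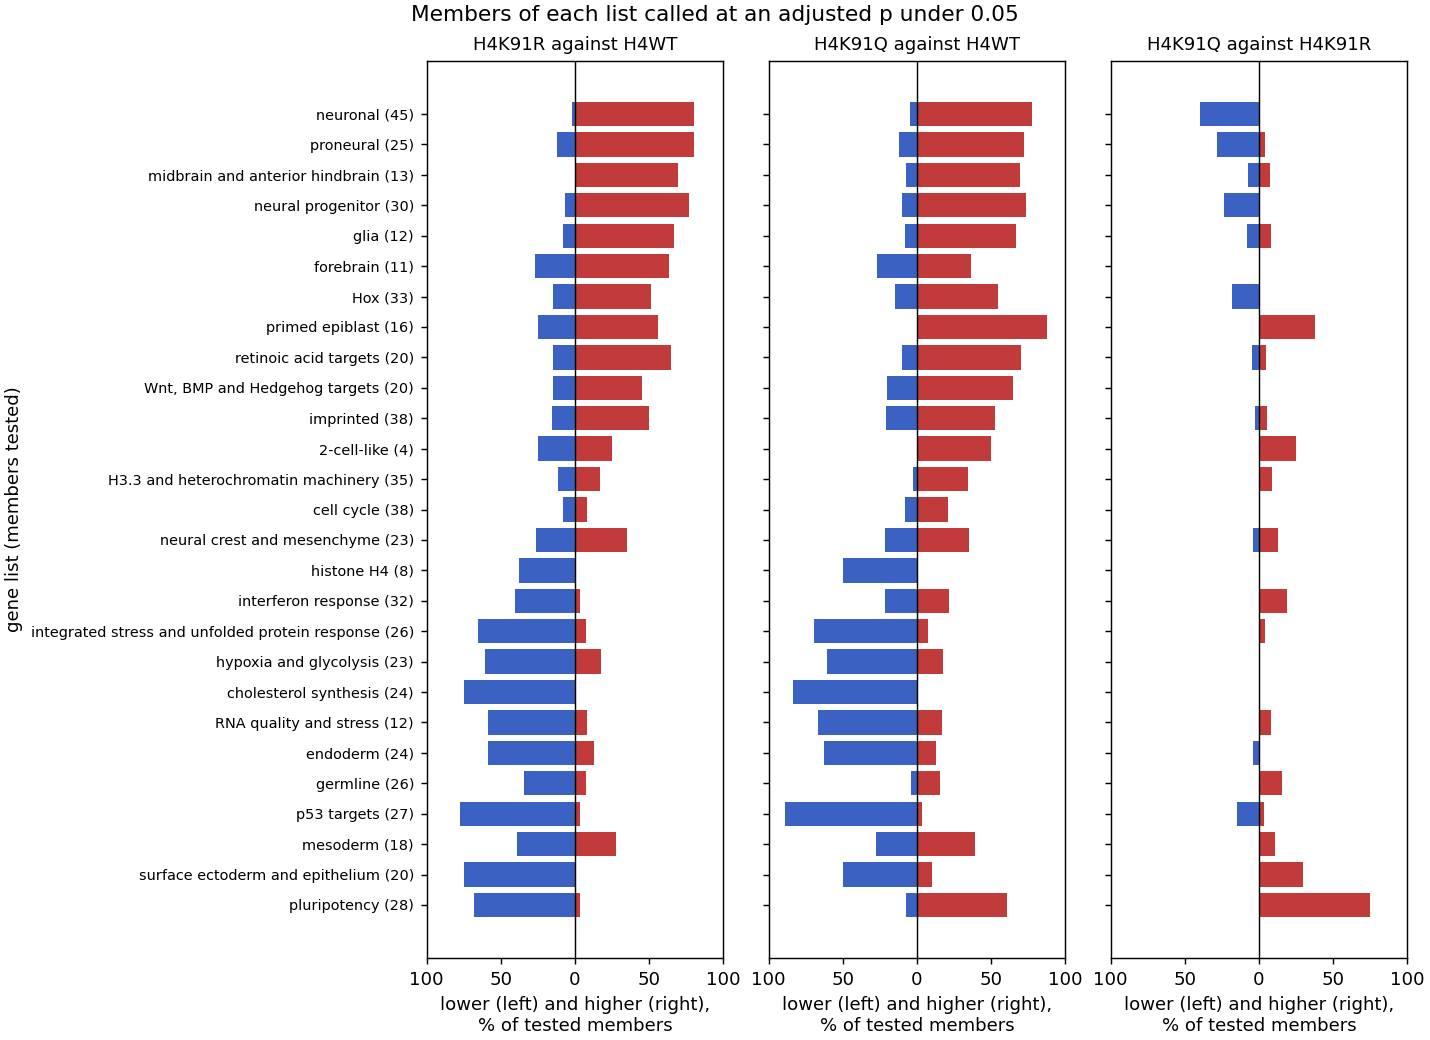
Share of the tested members of each of 27 gene lists that were lower (blue, left) or higher (red, right) at a Benjamini-Hochberg adjusted p below 0.05 (edgeR), with the number of tested members in parentheses. Of 45 neuronal genes, 36 rose in H4K91R and 35 in H4K91Q, and of 28 pluripotency genes 19 fell in H4K91R while 17 rose in H4K91Q.

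Histone H4 genes were compared because the transgenes encode H4. Poly(A) RNA was sequenced, so H4 transcripts without a poly(A) tail would be missed, and the counts may not stand for H4 expression. The transgene sequence is not given in the sources used here, so transgene reads may be counted on these genes. H4c18 (Entrez 319161, chromosome 13, 21831792 to 21832197) fell by 2.75 ± 0.29 on the log2 scale in H4K91R and by 3.07 ± 0.28 in H4K91Q, from 11.7 ± 0.911 CPM in H4WT. H4c8 fell by 1.67 ± 0.33 and 2.04 ± 0.32 on the log2 scale. H4c9 was at -0.39 ± 0.20 in H4K91R, which did not pass (edgeR, adjusted p = 0.125), and fell by 0.60 ± 0.20 on the log2 scale in H4K91Q (edgeR, adjusted p = 0.0234). The H4c9 call ended with library size scaling (adjusted p = 0.0794), without H4WT replicate 2 (0.087) or 3 (0.0598), and without H4K91Q replicate 1 (0.0845) or 2 (0.0593). H4c12 was at -0.15 ± 0.52 and -0.88 ± 0.53 and did not pass in either comparison. The histone H4 list did not pass. In H4K91R 0 of 8 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.283), and in H4K91Q 0 of 8 rose and 4 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.136). The values of H4c18, H4c12 and H4c8 are uncertain, since only 12.5%, 13.8% and 50% of their 31-base words occur in no other gene's transcripts. For H4c9 that share was 64.4%.

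The changes of the 2 mutants against H4WT were largely in the same direction. Of the tested genes, 2465 rose in both and 2867 fell in both, where independent lists would share 694 and 883. Part of the excess over independent lists may come from the shared H4WT libraries, since 3 controls cannot be split into 2 sets of 2. Across genes the log2 changes of the mutants correlated with r = 0.875, beside 0.530 in simulated unchanged groups with the same controls, and genes are not independent replicates. Their covariance was 0.472, beside a simulated 0.0199, a difference of 0.452. The sign was the same in 84.5% of genes, beside 67.4% in the simulation, which gave 0 shared calls. The simulation holds only the spread between libraries of a group. An offset of the H4WT line or culture would move both comparisons alike, so these values cannot show that the mutants act alike. Genes called in opposite directions numbered 31, of which 30 were higher in H4K91Q and lower in H4K91R. Among these 30 were Nanog at -0.93 and 2.11, Utf1 at -1.40 and 1.79, and Tdh at -1.13 and 1.14 in H4K91R and H4K91Q.

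The direct comparison of H4K91Q with H4K91R asked whether the mutants differ. Pluripotency genes were higher in H4K91Q, and neuronal genes were lower than in H4K91R. Nanog rose by 3.04 ± 0.26 on the log2 scale (SE, n = 3 libraries per group), from 2.23 ± 0.947 to 17.4 ± 4.28 CPM (mean ± SD). Trh, which encodes thyrotropin-releasing hormone (Entrez 22044, chromosome 6, 92242061 to 92244650), rose by 4.09 ± 0.48, and Otx2, a transcription factor of the epiblast and anterior brain (Entrez 18424, chromosome 14, 48656781 to 48667644), by 3.89 ± 0.39. Hes5, a Notch target of neural progenitors (Entrez 15208, chromosome 4, 154960626 to 154962372), fell by 1.05 ± 0.14 on the log2 scale, from 23.6 ± 1.66 to 11.5 ± 1.88 CPM. The adjusted p was 2.73e-04, 0.00112, 4.30e-04 and 0.00174 (edgeR, Benjamini-Hochberg). In all, 350 genes were higher and 411 lower in H4K91Q, 138 and 13 of them at least 2-fold. Most of the genes called here had also changed against H4WT, and 32 of the 761 had not in either mutant.

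The pluripotency list had 21 of 28 tested members higher and 0 lower in H4K91Q than in H4K91R (23 and 0 adjusted over the list alone), with a median of 2.03 (camera, adjusted p = 1.57e-21, and adjusted p = 0.0790 with an estimated correlation). Utf1, a chromatin factor of pluripotent cells (Entrez 22286, chromosome 7, 139943856 to 139945112), rose by 3.19 ± 0.31, and Tdh, threonine dehydrogenase of stem cells (Entrez 58865, chromosome 14, 63492347 to 63509092), by 2.27 ± 0.21. Pou5f1, the stem cell factor also called Oct4 (Entrez 18999, chromosome 17, 35506032 to 35510777), which was chosen after its values were seen, rose by 2.65 ± 0.26. It stood at 24.6 ± 9.15 CPM in H4WT, 9.91 ± 2.67 in H4K91R and 61.0 ± 15.0 in H4K91Q. Tdgf1 and Fgf4, growth factors of early embryos, rose by 3.51 ± 0.43 and 3.34 ± 0.51, and the zinc finger gene Zfp980 by 3.39 ± 0.40. Of the 31-base words of Zfp980, 17.2% occur in no other gene's transcripts. Within groups, the deviations of the 28 pluripotency genes from their group means had a mean pairwise correlation of 0.353 across libraries, beside 0.346 for the RNA quality and stress list and 0.303 for the neuronal list. Of the primed epiblast genes 6 of 16 rose and 0 fell (8 and 2 adjusted over the list alone, camera adjusted p = 3.78e-04, and adjusted p = 0.152 with an estimated correlation), with the DNA methyltransferase genes Dnmt3b at 2.07 ± 0.20 and Dnmt3l at 3.03 ± 0.45. Of the mesoderm genes 2 of 18 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00864, and adjusted p = 0.0884 with an estimated correlation), with T, or brachyury, at 2.43 ± 0.42. The mesoderm call ended without H4K91Q replicate 3 (adjusted p = 0.129). Of the surface ectoderm and epithelium genes 6 of 20 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.11e-07, and adjusted p = 0.152 with an estimated correlation), with Grhl2 at 2.21 ± 0.28 and Tfap2c at 1.37 ± 0.17. Of the germline genes 4 of 26 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 8.20e-05, and adjusted p = 0.0790 with an estimated correlation).

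Of the neuronal list, 0 of 45 rose and 18 fell (0 and 30 adjusted over the list alone) in H4K91Q relative to H4K91R (camera, adjusted p = 1.13e-12, and adjusted p = 0.152 with an estimated correlation), with L1cam, an adhesion protein of axons, at -0.74 ± 0.13. Of the neural progenitor list 0 of 30 rose and 7 fell (0 and 12 adjusted over the list alone, camera adjusted p = 8.20e-05, and adjusted p = 0.152 with an estimated correlation), with Ncan at -0.72 ± 0.11. Of the proneural list 1 of 25 rose and 7 fell (1 and 15 adjusted over the list alone, camera adjusted p = 1.81e-07, and adjusted p = 0.0790 with an estimated correlation). Of the Hox list 0 of 33 rose and 6 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.00661, and adjusted p = 0.194 with an estimated correlation), a call that ended without H4K91R replicate 3 (adjusted p = 0.0753). Of the interferon response genes 6 of 32 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 4.91e-09, and adjusted p = 0.0790 with an estimated correlation), with Ifit3 at 0.81 ± 0.14 and Psmb8 at 0.96 ± 0.16. Of the H3.3 and heterochromatin machinery 3 of 35 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00566, and adjusted p = 0.0790 with an estimated correlation). The cholesterol synthesis list lay at the threshold, with no member of 24 called and a median of -0.069 (camera, adjusted p = 0.04999, and adjusted p = 0.429 with an estimated correlation). Its call ended without H4WT replicate 1 or 3, without H4K91R replicate 1 or 3 and without H4K91Q replicate 1 (adjusted p from 0.0576 to 0.129). That call also ended with thinning (0.0635), fry (0.158) and the replicate block (0.0607).

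The remaining lists did not pass between the mutants. Of the p53 targets 1 of 27 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.212). Of the RNA quality and stress genes 1 of 12 rose and 0 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.736). In the glia list 1 of 12 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.201), and in the midbrain and anterior hindbrain list 1 of 13 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.0723). In the endoderm list 0 of 24 rose and 1 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.0627). In the neural crest and mesenchyme list 3 of 23 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.212). Of the imprinted genes 2 of 38 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.212), and of the 2-cell-like genes 1 of 4 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.160). Of the retinoic acid targets 1 of 20 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.453), with a median of -0.065 and a mean of 0.027. Of the integrated stress and unfolded protein response genes 1 of 26 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.679), with a median of -0.034 and a mean of 0.00297. No member passed in the forebrain, cell cycle, hypoxia and glycolysis, histone H4, and Wnt, BMP and Hedgehog lists over all genes tested. Adjusted over the list alone, 6 rose and 2 fell of 23 hypoxia and glycolysis genes, 1 rose and 1 fell of 20 Wnt, BMP and Hedgehog targets, and 0 passed in the other 3 lists. Their camera adjusted p was 0.0747, 0.155, 0.453, 0.481 and 0.359.

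The count of 761 moved with the library left out. It was 188 without H4K91R replicate 2, 410 without H4K91R replicate 1, 298 without H4K91Q replicate 1 and 202 without H4K91Q replicate 2. It was 1093 without H4K91Q replicate 3, and 682 to 793 without H4K91R replicate 3 or any 1 H4WT library. Of 62 calls of named genes, 24 were kept in each of the 9 fits that left out 1 library, and they include the genes named in this comparison. In the preset-correlation test 12 of the 27 lists passed, 7 upward and 5 downward, and none passed with an estimated correlation. With DESeq2's size factors in edgeR 304 genes were higher and 509 lower, and with DESeq2 itself 346 and 619.

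**Figure D3:**
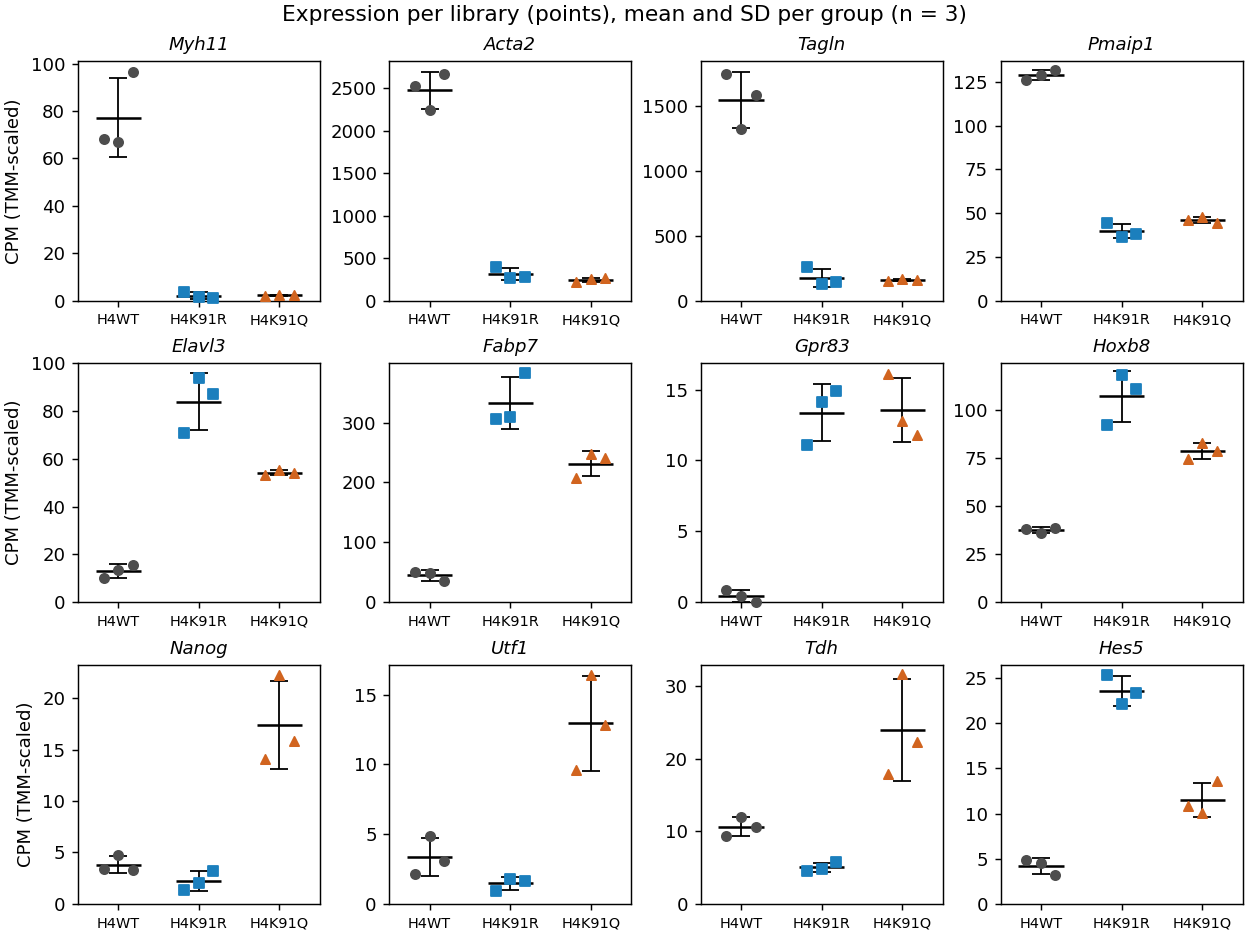
CPM (TMM-scaled, linear axes from 0) of 12 genes in each library (points), with the mean (line) and SD (bars) of each group (n = 3). Myh11, Acta2, Tagln and Pmaip1 are lower in both mutants, Elavl3, Fabp7, Gpr83 and Hoxb8 are higher in both, Nanog, Utf1 and Tdh are highest in H4K91Q, and Hes5 is highest in H4K91R.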

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

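The tests of a larger share of undifferentiated cells and of a copy gain, the thinning of libraries to equal totals and the choice of the chromosome 4 segment were chosen only after the result was seen. A direct test of the difference between the effects of the mutants picked out each value here (edgeR for genes, camera for lists, n = 3 libraries per group), and each value is H4K91Q relative to H4K91R on the log2 scale. It called 761 genes. Leaving out 1 library gave 188 (H4K91R replicate 2), 410 (H4K91R replicate 1), 298 (H4K91Q replicate 1), 202 (H4K91Q replicate 2) or 1093 (H4K91Q replicate 3), and 682 to 793 for the other 4 libraries. Lists that were higher in H4K91Q had medians of 2.03 (pluripotency), 0.45 (primed epiblast), 0.28 (mesoderm), 0.28 (surface ectoderm and epithelium), 0.22 (germline), 0.33 (interferon response) and 0.084 (H3.3 and heterochromatin machinery). Lists that were lower had medians of -0.26 (neural progenitor), -0.45 (proneural), -0.42 (neuronal), -0.20 (Hox) and -0.069 (cholesterol synthesis). The Hox call ended without H4K91R replicate 3 (adjusted p = 0.0753) and the mesoderm call without H4K91Q replicate 3 (0.129). That of cholesterol synthesis ended without H4WT replicate 1 (0.0576) or 3 (0.0576), H4K91R replicate 1 (0.0893) or 3 (0.129), or H4K91Q replicate 1 (0.127). It also ended with thinning (0.0635), fry (0.158) and the replicate block (0.0607). None of the 12 lists passed with an estimated correlation, where adjusted p ran from 0.0790 to 0.429.

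Of the named genes, 24 kept their call in each fit without 1 library. Among genes of pluripotent cells and the epiblast, Nanog stood at 3.04, Utf1 at 3.19, Tdh at 2.27, Pou5f1 at 2.65, Trh at 4.09, Otx2 at 3.89, Tdgf1 at 3.51, Fgf4 at 3.34, Dnmt3b at 2.07 and Dnmt3l at 3.03. Of the mesoderm list, Pecam1, an endothelial adhesion protein also made by stem cells, stood at 2.03 and T at 2.43. Of the surface ectoderm and epithelium list, Grhl2 stood at 2.21 and Tfap2c at 1.37. Whether these genes mark cell types apart from the pluripotent cells was not tested. The interferon response genes Psmb8 and Ifit3 stood at 0.96 and 0.81. Zinc finger genes of chromosome 4, Zfp980, Zfp987, Zfp985 and Zfp979, stood at 3.39, 2.31, 1.41 and 1.41. The neural genes Hes5, Ncan, L1cam and Aldoc stood at -1.05, -0.72, -0.74 and -0.64. Pou5f1, Zfp979, Zfp985 and Zfp987 were chosen after their values were seen.

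The other 38 named genes lost their call in at least 1 such fit. Neural genes among them were Elfn2 (-1.14), Slc6a11 (-1.07), Slc32a1 (-1.07), Pou3f2 (-0.58), Prdm8 (-0.75), St18 (-0.82), Elavl3 (-0.63), Celf3 (-0.84), Pax2 (-0.85), Lmx1a (1.26) and S100b (1.15). Eomes, placed in the proneural list, stood at 1.30. Hox genes were Hoxb8 (-0.44), Hoxb9 (-0.31) and Hoxa6 (-0.96). Genes of other lineages were Col4a2 (-0.39), Sfn (1.43), Ednrb (-0.57), Postn (0.61), Lum (1.14), Ddx4 (0.58), Rpl10l (1.98) and Piwil2 (1.15). Imprinted genes were Phlda2 (1.75), Peg13 (-0.39) and H19 (0.29). Genes of chromatin, stress and signals were Hells (0.34), Nasp (0.32), Plk3 (-0.57), Ptprv (-0.70), Cpt1c (-0.41), Parp9 (0.47), Ifi44 (0.55), Asns (0.35), Stra6 (-0.35), Cyp26b1 (1.06) and Junb (0.33). Ank1, an ankyrin, stood at -1.06. Without H4K91R replicate 1, 2 or 3, 24, 34 and 6 calls ended (highest adjusted p = 0.186, 0.169 and 0.0692, edgeR). Without H4K91Q replicate 1, 2 or 3, 27, 33 and 7 ended (0.134, 0.186 and 0.0934), and without H4WT replicate 1, 2 or 3, 2, 1 and 4 (0.0540, 0.0529 and 0.0630).

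Pluripotency genes were higher in H4K91Q than in H4K91R, with 21 of 28 called. A difference in sequencing depth is argued against, since 95.2% of the called members (20 of 21) stayed called in the same direction when the libraries were thinned to equal totals. A larger share of undifferentiated cells in H4K91Q cannot be told apart from regulation of these genes together within each cell. Within groups the members had a mean pairwise correlation of deviations of 0.353, above 1000 random lists matched on mean expression (highest 0.132), but RNA quality and stress (0.346), neuronal (0.303) and p53 target genes (0.301) came near it. An effect of the glutamine mutant on leaving pluripotency stays open as untested.

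Zinc finger genes of a segment of chromosome 4 (145464210 to 147812229) were higher in H4K91Q than in H4K91R, with 9 of 16 tested genes called and a median of 1.29. Against H4WT, 10 of the 16 were lower in H4K91R, and 9 were higher and 1 lower in H4K91Q. A gain of copies of the whole segment as the only cause is argued against, since its genes did not rise by 1 factor. Of its tested genes 6 had an upper 95% limit below that median, and Zfp982 stood at 0.22 ± 0.10 beside 1.41 ± 0.19 for Zfp979. A smaller gain beside other changes was not tested. Reads shared between near-identical genes cannot be told apart from separate changes. Only 3 of the 9 called genes have over 50% of their 31-base words in no other gene's transcripts and 3 have under 10%, with a range of 4.29% to 67.8%, and an effect of the mutants on this segment stays open as untested.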

How the results depend on the processing

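Thinning each library to the smallest total was chosen after seeing the data, and the other alternatives were not. The counts of changed genes stayed within 1.5 times their value under RLE, library size only, both other filters, DESeq2, limma-voom, the compared groups only and thinning. With an absolute log2 change of at least 1 they fell by construction to 2032 (H4K91R against H4WT), 1853 (H4K91Q against H4WT), 151 (H4K91Q against H4K91R), 2365 (3 groups) and 1465 (both mutants). Without 1 library they ran from 5851 to 6835, 5837 to 6961, 188 to 1093, 6356 to 7691 and 4583 to 5124. The cause of the range between the mutants was not tested. With an estimated correlation 0 of 19, 18 and 12 lists passed, for which the cause was not tested, and fry called 23, 23 and 12. The lists passing without 1 library ran from 17 to 19, 17 to 19 and 10 to 14. Under the replicate block the counts were 6751, 6840, 1011, 7412 and 5328. The block also ended the calls of cholesterol synthesis between the mutants (0.0607) and of Sp110 in H4K91R (0.0583). The labels give the samples only a shared number. Of 9 same-number pairs 5 had a correlation of deviations above 0.1 (-0.163 to 0.198). Of 9 libraries 3 correlated best with their own number in both other groups, each of them a replicate 1 (0.172 to 0.198). Between H4WT and H4K91Q the same-number pairs had 0.172, 0.198 and 0.141, and the highest unlike pair 0.0359. Between H4WT and H4K91R the same-number pairs had 0.174, 0.0107 and -0.163, and the highest unlike pair 0.265. Between the mutants the same-number pairs had 0.198, -0.0518 and -0.0257, and the highest unlike pair 0.223. Both of these unlike pairs lay above every same-number pair, so the values leave pairing open. Of 261 called values of named genes, none changed sign, and 1 to 10 lost the call under a setting that kept all libraries and set no minimum change. Of 49 list calls, library size only ended 5, thinning 3, and fry and the block 1 each. Thinned counts gave 6330, 6189 and 565 genes, so fewer were called in each comparison at the smallest depth. For 10 pairs of a named gene and a setting, the filter left no value.

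The values that changed sign had not passed in either setting, and the cause was not tested. Ranges are without 1 library. In H4K91R against H4WT these were H4c12 (-0.92 to 0.41, and 0.033 with library size only) and the neural crest and mesenchyme median (-0.079 to 0.10, and 0.13 with library size only). Between the mutants they were H4c12 (-1.08 to 0.046), H4c8 (-0.61 to 0.014), H4c9 (-0.34 to 0.13), H4c18 (-0.66 to 0.028, and 0.017 when thinned) and the medians of glia (-0.0067 to 0.18), histone H4 (-0.48 to 0.13), p53 targets (-0.12 to 0.015), integrated stress and unfolded protein response (-0.055 to 0.029) and RNA quality and stress (-0.17 to 0.068). The neural crest and mesenchyme median ran from -0.050 to 0.20, with -0.00598 under RLE and -0.039 when thinned, and that of hypoxia and glycolysis was -0.000277 under RLE.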

Other observations

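The contractile, collagen, YAP target and protocadherin groups described here were listed only after their values were seen, and the tests of a lower share of mesenchymal cells and of chromosome medians and the thinning of libraries were chosen only after the result was seen. Of the contractile genes of smooth muscle, 19 of 19 tested were called lower in each mutant (edgeR, n = 3 libraries per group). Their medians were -1.54 in H4K91R and -1.59 in H4K91Q on the log2 scale. Cnn1, which encodes calponin (Entrez 12797, chromosome 9, 22099221 to 22109221), changed by -3.22 ± 0.15 and -3.58 ± 0.15 (SE), from 52.9 ± 5.53 CPM in H4WT (mean ± SD). Of 20 collagen and fibroblast genes, 10 were higher and 4 lower in each mutant, with medians of 0.32 and 0.38, and Col6a2, a collagen of the cell surface matrix (Entrez 12834, chromosome 10, 76595756 to 76623630), changed by 1.75 ± 0.13 and 1.34 ± 0.13. Some matrix and fibroblast genes outside this group fell with the contractile genes, with Lox at -3.78 and -3.01, Ltbp2 at -4.01 and -3.85, Fn1 at -2.32 and -2.81, and Thy1 at -0.96 and -1.13 (the last 2 named after their values were seen). Of 22 targets of YAP, a regulator that answers cell tension and density, 17 were lower and 0 higher in H4K91R, and 18 were lower and 1 higher in H4K91Q, with medians of -0.84 and -0.90. Of the 12 RNA quality and stress genes, 7 and 8 were lower and 1 and 2 higher, so an effect of handling on the YAP targets was not separated. Ankrd1 (Entrez 107765, chromosome 19, 36111965 to 36119844) changed by -2.86 ± 0.30 and -3.39 ± 0.30, and Ccn2 (Entrez 14219, chromosome 10, 24595442 to 24598683) by -2.38 ± 0.18 and -2.54 ± 0.18. The fixed lists hold 2 of the contractile, 11 of the collagen and fibroblast and 0 of the YAP target genes.

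Clustered protocadherins, adhesion proteins that give neurons an identity, lie in clusters on chromosome 18. In the alpha cluster (36930285 to 37187663) 10 of 11 tested genes were higher in H4K91R and 8 in H4K91Q, with medians of 1.88 and 1.19. In the beta cluster (37294840 to 37521419) 17 and 13 of 20 were higher, with medians of 1.36 and 0.83, and Pcdhb3 (Entrez 93874, chromosome 18, 37300799 to 37304585) changed by 1.65 ± 0.21 and 1.37 ± 0.21. In H4WT the alpha genes stood at 0.295 (Pcdha11) to 2.56 CPM (Pcdha3), and the beta genes at 0.161 (Pcdhb8) to 15.0 CPM (Pcdhb22). A count of 0 allows up to 0.367 CPM in H4WT replicate 3, so changes of the lowest genes are uncertain. In the gamma cluster (37661775 to 37841873) 7 of 22 were higher and 4 lower in H4K91R, and 2 were higher and 9 lower in H4K91Q. Its medians were 0.21 and -0.13, and the latter turned to 0.038 with library size scaling. In the beta cluster a median of 88.2% of a gene's 31-base words occur in no other gene's transcripts, which leaves little room for shared reads there. The median was 35.5% in the alpha and 44.6% in the gamma cluster.

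Contractile genes fell and neuronal genes rose in both mutants. A difference in sequencing depth is argued against, since 96.3% of the members called in both mutants (52 of 54) stayed called in the same direction after thinning to equal totals. A gain or loss of whole chromosomes as a direct shift of these genes is argued against. The largest absolute chromosome median (0.103 in H4K91R and 0.086 in H4K91Q) was at most 5.46% of the median absolute change of these members (1.99 and 1.58). Effects of such a change on genes of other chromosomes, or a change in part of the cells, were not tested. A lower share of mesenchymal cells as the only change cannot be told apart from a smaller share of contractile cells alone or from lower contractile genes within cells. Of the fixed neural crest and mesenchyme list 78.3% (18 of 23) had a lower 95% limit above the contractile median in both mutants, or 85.7% (18 of 21) without its contractile members Acta2 and Tagln, so the outcome against a bound of 80% turns on those 2 genes, and an effect of the mutants stays open as untested.

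The libraries were also regrouped. Of 100 splits of the 9 libraries, drawn from 280, 1 gave as many genes as the real groups (7470), and the highest other gave 5618. If the libraries are independent, this argues against 9 alike libraries divided at random. Of the 99 other splits 3 called any gene (5203 to 5618), and these 3 kept the H4WT libraries together. The rank of the real groups thus rests mostly on H4WT standing apart, and it cannot exclude an offset of a line or culture. For genes changed in both mutants 1 of 100 splits gave as many as the real groups (5332), with 4955 as the highest other. That other split kept the H4WT libraries as the control and mixed the libraries of the mutants. Splits that did not keep H4WT as the control gave 0 shared calls. The count thus shows that H4WT stood apart, and it cannot decide whether the mutants share an effect. The 10 splits of the 6 libraries of each pair of groups are too few for a share under 0.05. For genes the real values were 6797, 6830 and 761 for H4K91R against H4WT, H4K91Q against H4WT and H4K91Q against H4K91R, each reached by 1 of 10 splits, and the highest other was 0. For lists the real values were 19, 18 and 12, reached by 1, 1 and 2 of 10 splits, and the highest others were 15, 17 and 16. The medians of the other splits were 8, 11 and 8 lists, although these splits called 0 genes.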
